A study of Mus musculus with 12 samples.

How the data were processed

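RNA was measured in thoracic aortas of C57BL/6J mice, cleaned of fat and frozen, with RNA isolated with the RNeasy Plus kit, SMART-Seq v4 libraries and Illumina sequencing. Per the labels, the authors counted reads per gene with HTSeq against the mouse build mm9, and the deposited counts are raw whole numbers per gene symbol. The aligner, the gene annotation and the program versions are not given in the sources used here. Beside the counts, the authors deposited a table of nicotine against air for each genotype, holding a log2 fold change and its standard error in log2 units. Per the file headers, these deposited tables also hold a test score (the log2 fold change over its standard error) and an unadjusted and an adjusted p-value. Their columns are named as DESeq2 names them, but the program is not stated. Each deposited table lists 17223 genes, which are those with a total over 20 counts across all 12 libraries. For WT, 23 gene names had been turned into dates and were not matched.

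Every library was taken from its label into 1 of 4 groups (WT air, WT nicotine, KO air, KO nicotine) of 3. Library numbers are unique and the groups share none, so the libraries could not be paired. The labels do not state that each library is a separate mouse. The p-values therefore measure the spread between libraries, part of which may be technical. No batch, date or lane is given. The KO libraries carry numbers 1 to 5 and 7 and the WT libraries 6 and 8 to 12, so the numbers nearly separate the genotypes. What the numbers stand for is not stated. If they follow an order of handling, an effect of it cannot be told apart from genotype. Library totals and the share of mitochondrial genes (13 genes) were computed from the counts. Between pairs of libraries in a group, the chi-square per degree of freedom ran from 8.52 to 71.5. Each pair therefore differed by more than the chance of counting reads, so none was the same library sequenced again. No known repeat was at hand for comparison, so these values cannot tell whether separate preparations of the same sample are among the libraries.

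Of 27933 genes in the table, 14621 passed edgeR's filterByExpr and were tested. Counts were scaled by TMM (normalisation factors 0.962 to 1.05) and fitted with edgeR 4.0.16's robust quasi-likelihood model with 4 group means and 8 residual degrees of freedom, and the biological coefficient of variation was 0.233. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors are the absolute log2 fold change over the square root of F. Contrasts were nicotine in WT, nicotine in KO, their difference (the interaction), KO against WT in each exposure, and nicotine averaged over genotypes. CPM are TMM-scaled, and log2 scores used a prior count of 2. The median standard error was 0.16 for the average.

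The gene lists, 38 with at least 3 tested members, were written before the data were examined, as were the comparisons, the tests, the rule for named genes and most alternatives. They were tested with limma 3.58.1's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Genes are named by a rule. Per comparison, it took up to 10 genes in each direction by fold change among those past the threshold, with at least 5 CPM in the higher group and no overlap between libraries, skipping predicted or unnamed genes. Where fewer than 3 passed in a direction, it took the 5 with the smallest unadjusted p. Some genes that the rule takes are not reported here. It added up to 4 members of each list past its test, up to 4 members past 0.05 adjusted over the list alone, and always Chrna7, the other tested nicotinic subunits, Acta2, Myh11, Adipoq and Ucp1. A hepatocyte list of 29 genes was added after liver transcripts had been seen. Scores per library were compared by exact permutation with Benjamini-Hochberg adjustment over 42 measures per contrast.

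Alternatives were DESeq2 1.42.0, limma voom, other size factors, other filters on low counts, no robust fit, a minimum fold change, only the compared groups, an adipocyte covariate, 1 surrogate variable (sva 3.50.0), thinned counts and leaving out each library of the groups compared. Alternatives added after the data were seen were the hepatocyte and immediate early covariates, DESeq2 with only the compared groups, and the WT calls without KO nicotine 3. R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.

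The procedure was tested on simulated counts, drawn for each gene independently around its mean over all libraries, with dispersions estimated from these data. The simulation holds no correlation between genes and no differences in tissue content between libraries. Its recovered and false calls, of genes and of lists, may therefore not carry over to the real libraries. With nicotine in WT it recovered 62 of 100 genes changed 2-fold and 96 of 100 changed 4-fold, with 7 false calls, where DESeq2 recovered 74 and 99 with 29 false calls and voom 53 and 95 with 7. For the interaction it recovered 29 and 93 of 100, with 4 false calls. A list raised 1.5-fold passed camera with a preset correlation (adjusted p = 4.44e-12), with an estimated correlation (adjusted p = 0.00676) and fry (adjusted p = 0.00567), with 0 other lists called.

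Genes are identified by symbol only. The reference annotation at hand is of another build than the counts, so no positions are given and it was used only for the order of genes around Chrna7. The libraries do not mark the strand, so counts of overlapping genes are uncertain, as are those of near-identical copies such as Hspa1a and Hspa1b. The deposited columns of mean expression in the comparison tables were not used here. Raw reads were not analysed here.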

Results

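RNA of the mouse thoracic aorta was sequenced and counted per gene in 12 libraries that fall into 4 groups of 3. Wild-type (WT) C57BL/6J mice and mice labelled as knockouts (KO) of the alpha7 nicotinic acetylcholine receptor, an ion channel encoded by Chrna7, breathed room air or nicotine vapor. Exposure lasted 12 weeks from 5 months of age, and the aortas were taken at 8 months. Libraries are named here by group and by the number in their label: WT air 8, 9 and 10, WT nicotine 6, 11 and 12, KO air 1, 2 and 7, and KO nicotine 3, 4 and 5. The total count per library ran from 10240031 (WT nicotine 6) to 12628323 (WT air 9), and 17995 to 19484 genes had a count. Mitochondrial genes took 3.0 to 7.52% of the counts, with both extremes in the WT air group. At this depth and spread, the median standard error of a log2 fold change was 0.22 between groups and 0.31 for the interaction of nicotine and genotype.

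Chrna7, the gene named in the knockout label, was scarce in every library and was not measurably lower in the KO libraries. Raw counts were 22, 35 and 37 in WT air, 9, 18 and 26 in WT nicotine, 26, 18 and 28 in KO air, and 25, 8 and 21 in KO nicotine. Scaled to CPM (edgeR's library-scaled counts), the means were 2.59 ± 0.591 in WT air, 1.51 ± 0.619 in WT nicotine, 2.02 ± 0.420 in KO air and 1.58 ± 0.770 in KO nicotine (SD, n = 3 each). The KO against WT log2 fold change of Chrna7 was -0.36 ± 0.45 (SE) in air and 0.07 ± 0.47 in nicotine, neither past the edgeR threshold. The labels do not state which part of the gene was removed, and a count over the whole gene can include reads from exons outside a deletion. These counts therefore do not check the genotype, and KO below means the libraries labelled KO. Of the other nicotinic receptor subunits, Chrna1, Chrna2, Chrnb1 and Chrnb2 had enough counts to be tested. None of the 5 tested subunits passed the edgeR threshold in any comparison.

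The first comparison asked how nicotine vapor changed the aorta of WT mice. Has1, which encodes a hyaluronan synthase, rose 4.28-fold, from 1.99 ± 0.243 CPM in air to 8.57 ± 1.30 CPM in nicotine (SD, n = 3 each). Its log2 fold change was 2.10 ± 0.27 (SE), with an edgeR adjusted p of 0.0190. Errfi1, a feedback inhibitor of epidermal growth factor receptor signalling, rose 4.15-fold from 94.1 ± 23.4 to 391 ± 116 CPM (log2 fold change 2.05 ± 0.26, edgeR adjusted p = 0.0190). Rcan1, an inhibitor of calcineurin, rose 2.43-fold from 28.7 ± 2.23 to 69.7 ± 12.6 CPM (log2 fold change 1.28 ± 0.17, edgeR adjusted p = 0.0190). In all 3 genes each nicotine library lay above each air library. No gene fell past the threshold. Among genes with lower values in nicotine, the lowest unadjusted p belonged to Zfp810 (log2 fold change -0.91 ± 0.19), Bcl9 (-0.61 ± 0.13), Bves (-1.02 ± 0.23), the sodium-calcium exchanger gene Slc8a3 (-1.14 ± 0.26) and Fam212b (-1.15 ± 0.26), none of them past it.

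**Figure D1:**
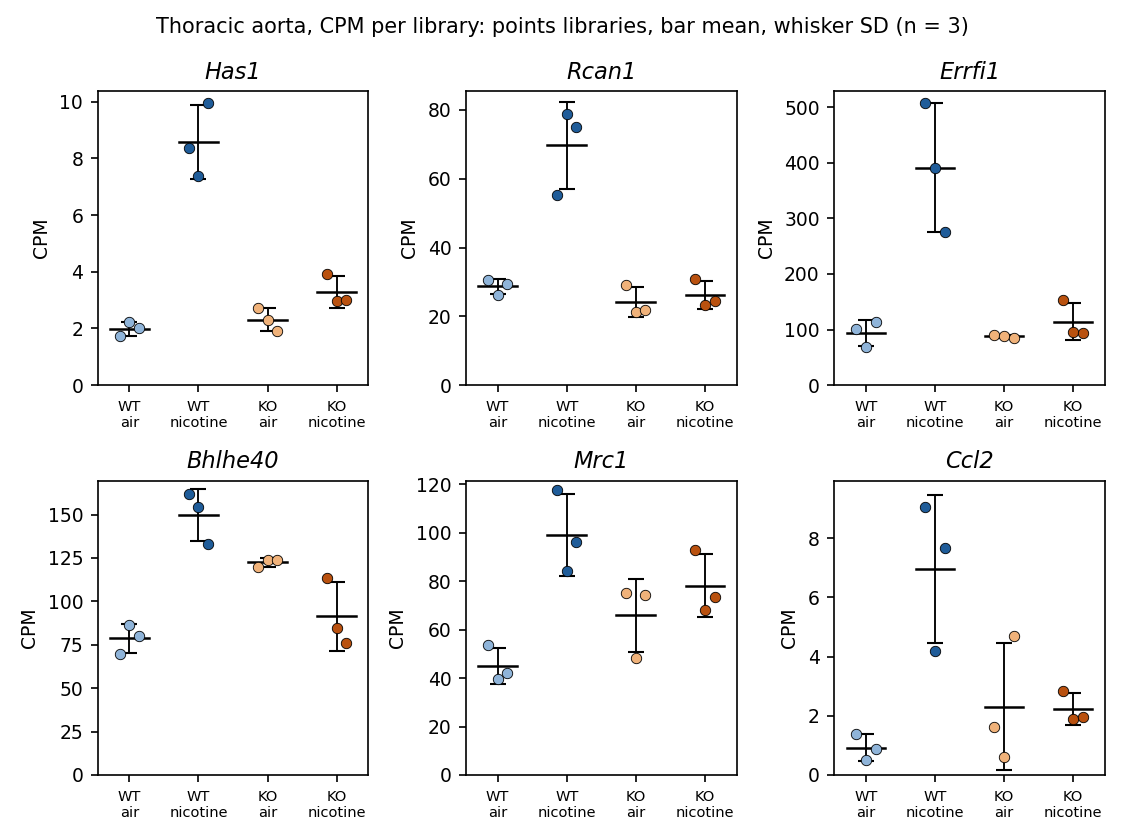
CPM (vertical axis, linear from 0) of Has1, Rcan1, Errfi1, Bhlhe40, Mrc1 and Ccl2 in the 4 groups (horizontal axis), with a point per library, a bar for the mean and a whisker for the SD of 3 libraries. The WT nicotine libraries lie above the WT air libraries in all 6 panels, and Has1, Rcan1 and Errfi1 passed the edgeR threshold.

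Macrophage, cytokine and neutrophil lists rose with nicotine in WT by camera, a test that compares a list with the other genes, though none of the 3 passed with an estimated correlation (adjusted p = 0.304, 0.144 and 0.337). T cell (camera adjusted p = 0.841), B cell (0.878) and red cell markers (0.270) did not pass. The rise was not limited to these lists. Fibroblast markers (12 of 12 above 0, median 0.26, camera adjusted p = 3.63e-05), interferon-stimulated genes (15 of 18, median 0.46, 0.00230), class II antigen presentation genes (7 of 7, median 0.78, 0.00230) and mesothelial markers (9 of 9, median 0.82, 0.0296) also rose, none of them with an estimated correlation (adjusted p = 0.499, 0.499, 0.499 and 0.677). The last 3 of these 4 calls ended without 1 library, interferon-stimulated genes without WT nicotine 6 (camera adjusted p = 0.176), class II without WT air 8 (0.0693) or WT nicotine 6 (0.0751), and mesothelial markers without WT air 8 (0.124), WT air 10 (0.0693) or WT nicotine 12 (0.0748). With the adipocyte score of each library as a covariate the interferon (0.0826) and mesothelial calls (0.0675) ended as well. All 19 tested macrophage markers had a log2 fold change above 0, with a median of 0.79. Macrophage markers had a camera adjusted p of 1.16e-16 (adjusted p = 0.304 with an estimated correlation). None passed over all genes, and 9 rose when adjusted over the list alone. These included the mannose receptor gene Mrc1 (log2 fold change 1.14 ± 0.19), the Fc receptor gene Fcgr3 (1.12 ± 0.24), Csf1r (0.90 ± 0.20) and Lyve1 (0.88 ± 0.24). Of 19 cytokine, chemokine and adhesion genes, 18 were above 0, with a median of 0.67. Cytokine genes had a camera adjusted p of 5.23e-12 (adjusted p = 0.144 with an estimated correlation). None of them passed over all genes and 10 rose when adjusted over the list alone, among them Ccl2 (2.90 ± 0.63), Cxcl1 (2.01 ± 0.42), the E-selectin gene Sele (2.0 ± 0.47) and Ccl11 (0.67 ± 0.17). The 7 neutrophil markers had a median of 2.24 and a camera adjusted p of 3.63e-05 (adjusted p = 0.337 with an estimated correlation). S100a9 (2.24 ± 0.71) and Cxcr2 (2.34 ± 0.77) rose when adjusted over the list alone, with none over all genes. The neutrophil score, the mean log2 CPM of the list in a library, was 1.95, -0.19 and 0.77 in WT nicotine 6, 11 and 12 and -0.53, 0.01 and -0.79 in WT air 8, 9 and 10, so WT nicotine 11 lay within the air range. The score difference of 1.28 became 0.72 without WT nicotine 6.

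Genes of acute responses also had higher values with nicotine in WT. All 22 immediate early genes, which are induced within minutes of a stimulus, were above 0, with a median of 0.85. Immediate early genes had a camera adjusted p of 4.99e-14 (adjusted p = 0.337 with an estimated correlation). Over all genes 0 members passed, while Fosl2 (1.23 ± 0.21), Klf4 (0.85 ± 0.17) and Egr2 (2.95 ± 0.64) rose when adjusted over the list alone. All 14 glucocorticoid-responsive genes were above 0, with a median of 0.69. The score of this list was higher in each WT nicotine library than in each WT air library. Zbtb16 and Fkbp5 were less uniform. In WT nicotine 6 and 11, Zbtb16 was at 97.0 and 111 CPM, below WT air (165 to 217 CPM). Fkbp5 was there at 58.1 and 62.8 CPM, also below WT air (63.6 to 113 CPM). Only WT nicotine 12 lay above the air range, at 383 CPM for Zbtb16 and 167 CPM for Fkbp5. Glucocorticoid-responsive genes had a camera adjusted p of 1.26e-07 (adjusted p = 0.144 with an estimated correlation). Errfi1 passed over all genes, and Errfi1, Tsc22d3 (0.75 ± 0.20) and Per1 (0.68 ± 0.20) rose when adjusted over the list alone. The 15 heat shock genes had a median of 0.46 and a camera adjusted p of 0.000127 (adjusted p = 0.499 with an estimated correlation), which became 0.105 without WT nicotine 12. Dnajb1 (2.17 ± 0.48) and Bag3 (1.0 ± 0.25) rose when adjusted over the heat shock list alone, with none over all genes. The circadian clock list did not pass (camera adjusted p = 0.240), with a median of -0.05 against a mean of 0.14. Its member Bhlhe40 rose when adjusted over the list alone (0.93 ± 0.15, from 78.7 ± 8.54 to 149.9 ± 14.9 CPM, n = 3 each).

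Contractile smooth muscle genes were the 1 list that fell with nicotine in WT. Of 17 members, 15 were below 0, with a median of -0.43. Contractile genes had a camera adjusted p of 1.17e-06 (adjusted p = 0.499 with an estimated correlation), which became 0.0863 with the adipocyte score as a covariate. The contractile score difference of -0.34 became -0.22 without WT air 9. Acta2 was at -0.49 ± 0.24, Lmod1 at -0.67 ± 0.22 and Tpm2 at -0.54 ± 0.20, and no member passed over all genes or adjusted over the list alone. Markers of fat moved with these groups, 16 of 17 general adipocyte markers being above 0, with a median of 0.71. Adipocyte markers had a camera adjusted p of 2.27e-05 (adjusted p = 0.499 with an estimated correlation) and no member past the threshold over all genes or adjusted over the list alone. Adipoq was at 146 ± 110 CPM in WT air and 289 ± 58.4 CPM in WT nicotine (SD, n = 3 each), a log2 fold change of 0.98 ± 0.58, while the brown fat gene Ucp1 was at -0.10 ± 0.53. The adipocyte score was 8.20, 6.26 and 7.09 in WT air 8, 9 and 10, so WT air 8 lay above all 3 nicotine libraries (8.15, 8.11 and 8.01). The adipocyte score difference of 0.91 became 0.44 without WT air 9 and 1.41 without WT air 8. Oxidative phosphorylation genes had a median of 0.23 and a camera adjusted p of 0.0113 (adjusted p = 0.748 with an estimated correlation), and they turned downward with the adipocyte covariate (camera adjusted p = 3.72e-12). That call also ended without WT air 9 (camera adjusted p = 0.856), WT air 10 (0.108), WT nicotine 11 (0.167) or WT nicotine 12 (0.105). Fatty acid oxidation genes had a median of 0.34 and a camera adjusted p of 0.0141 (adjusted p = 0.703 with an estimated correlation), and they also turned downward with it (camera adjusted p = 8.94e-07). Their call ended without WT air 9 (camera adjusted p = 0.849), WT air 10 (0.0725), WT nicotine 11 (0.134) or WT nicotine 12 (0.103). Skeletal muscle markers were above 0 in 11 of 13, with a median of 0.82. Skeletal muscle markers had a camera adjusted p of 0.00651 (adjusted p = 0.635 with an estimated correlation), which became 0.0693 without WT air 8, 0.165 without WT nicotine 12 and 0.166 with the adipocyte covariate.

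In all, edgeR called 3 genes higher and 0 lower with nicotine in WT, out of 14621 tested. At an unadjusted p under 0.05 there were 1439 genes, where 731 is the mean expected if no gene differed. Genes are not independent, and how far this count varies by chance was not computed. An excess over 731, here or in the comparisons below, therefore does not exclude chance. Camera called 19 lists up and 1 down of 38, and none passed with an estimated correlation (lowest adjusted p = 0.144) or by fry (lowest adjusted p = 0.0611). The gene count was 34 without WT air 8, 0 without WT air 9, 1 without WT nicotine 6, 0 without WT nicotine 11, 14 without WT nicotine 12 and 6 without KO nicotine 3. Without WT air 10, Errfi1 kept its call (edgeR adjusted p = 0.0494), while Has1 and Rcan1 did not (0.0695 each). The gene count was 0 with the adipocyte score or the immediate early score as a covariate or with the WT libraries alone, 7 with DESeq2 size factors, 21 without the filter on low counts, 3 with limma voom, and 99 with DESeq2 (80 higher, 19 lower). The log2 fold changes of Errfi1, Has1 and Rcan1 were 2.06, 2.10 and 1.28 with the WT libraries alone. Without WT air 9 they were 1.87, 2.18 and 1.22.

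The second comparison asked the same of the mice labelled KO, where no gene passed. Has1 stood at 2.31 ± 0.411 CPM in KO air and 3.30 ± 0.557 CPM in KO nicotine (SD, n = 3 each), Rcan1 at 24.0 ± 4.35 and 26.1 ± 4.09 CPM, and Errfi1 at 88.1 ± 3.0 and 114 ± 33.5 CPM. Among genes with higher values in nicotine, the lowest unadjusted p belonged to Zfp407 (log2 fold change 0.55 ± 0.12), the glucocorticoid-induced leucine zipper gene Tsc22d3 (0.93 ± 0.20), Smpd3 (0.80 ± 0.19), Fam126b (0.51 ± 0.13) and Plxna2 (0.59 ± 0.15). Genes with lower values and a low unadjusted p included the immunoglobulin joining chain gene Jchain (-2.60 ± 0.60), Dync2li1 (-0.73 ± 0.19), the angiopoietin gene Angpt2 (-0.63 ± 0.18) and Gja6 (-1.04 ± 0.30). The lowest edgeR adjusted p of the comparison was 0.878, and 669 genes had an unadjusted p under 0.05 against 731 expected. EdgeR called 0 genes, limma voom 0 and DESeq2 on all 12 libraries 0, while DESeq2 on the 6 KO libraries called 7.

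Contractile smooth muscle genes fell as a list with nicotine in KO, 16 of 17 being below 0, with a median of -0.35. Contractile genes here had a camera adjusted p of 8.09e-08 (adjusted p = 0.706 with an estimated correlation). Lmod1 was at -0.61 ± 0.22 and Myl9 at -0.45 ± 0.20, and no member passed over all genes or adjusted over the list alone. The contractile score was 9.64, 9.68 and 10.20 in KO nicotine 3, 4 and 5 and 10.27, 10.11 and 10.17 in KO air 1, 2 and 7, so KO nicotine 5 lay within the air range, and the difference of -0.34 became -0.52 without it. General adipocyte markers were above 0 in 16 of 17, with a median of 0.61 and a camera adjusted p of 0.00448 (adjusted p = 0.840 with an estimated correlation). The adipocyte call ended without KO air 1 (camera adjusted p = 0.126) and without KO nicotine 4 (camera adjusted p = 0.892, downward). Skeletal muscle markers rose, 12 of 13 being above 0, with a median of 2.15. Their camera adjusted p was 1.11e-06 (adjusted p = 0.706 with an estimated correlation). None passed over all genes and 7 rose when adjusted over the list alone, among them Acta1 (2.44 ± 0.79), Mylpf (2.06 ± 0.67) and Tnnt3 (2.15 ± 0.70). The fast myosin gene Myh4 was at 99.7, 19.2 and 0.405 CPM in KO nicotine 3, 4 and 5 and at 1.02, 1.37 and 0.0825 CPM in KO air 1, 2 and 7, so 1 of the 3 nicotine libraries lay within the air range. The skeletal muscle score difference of 1.24 became 0.44 without KO nicotine 3 and 2.01 without KO nicotine 5. Glucocorticoid-responsive genes rose, 12 of 14 being above 0, with a median of 0.53 and a camera adjusted p of 7.68e-05 (adjusted p = 0.706 with an estimated correlation). Tsc22d3 rose when adjusted over the list alone, with none over all genes. Class II antigen presentation genes fell, 7 of 7 being below 0, with a median of -0.79 and a camera adjusted p of 3.21e-05 (adjusted p = 0.706 with an estimated correlation). H2-Aa was at -0.77 ± 0.37 and Cd74 at -0.80 ± 0.39, and no member passed over all genes or adjusted over the list alone. The class II score difference of -0.71 became -0.37 without KO air 7 and -0.46 without KO nicotine 5. B cell markers fell, 7 of 7 being below 0, with a median of -0.77 and a camera adjusted p of 0.000228 (adjusted p = 0.706 with an estimated correlation). Jchain fell when adjusted over the list alone, with none over all genes. Camera called 9 lists up and 6 down, against 3 up and 8 down with the adipocyte covariate, 5 up and 10 down without KO nicotine 3 and 6 up and 4 down without KO air 1. None passed with an estimated correlation (lowest adjusted p = 0.706) or by fry (lowest adjusted p = 0.868).

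**Figure D2:**
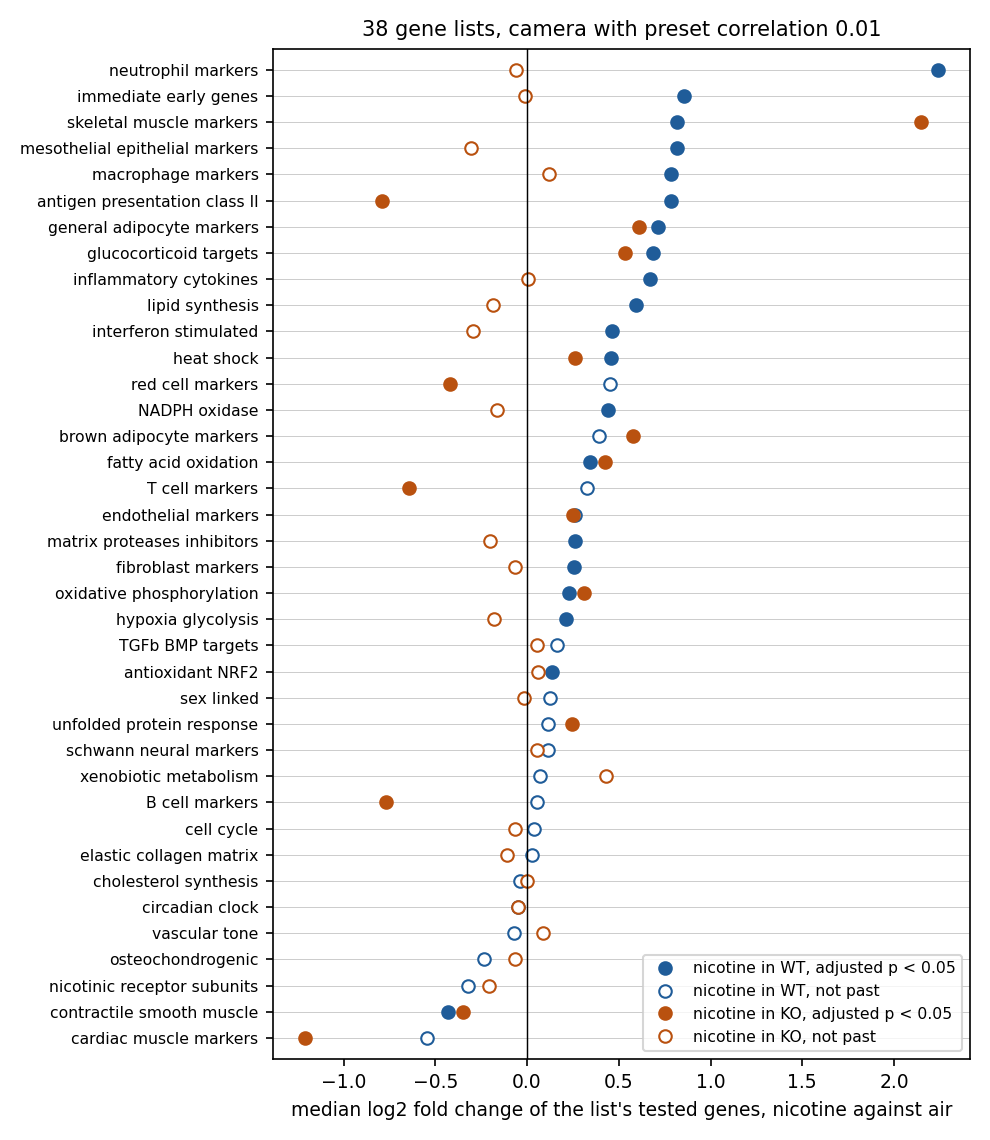
Median log2 fold change of nicotine against air (horizontal axis) over the tested genes of each of 38 lists (vertical axis), in WT and in KO libraries, with filled points for lists past camera with a preset correlation (adjusted p under 0.05) and open points for the rest. The macrophage list lies at 0.79 in WT and the contractile smooth muscle list at -0.43 in WT and -0.35 in KO, and no list passed with an estimated correlation.

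The interaction compared the nicotine effect in KO with that in WT, which bears on the question in the study's title, whether the alpha7 receptor mediates effects of inhaled nicotine. No gene passed. The 3 genes called in WT had smaller values in KO, with log2 fold changes of 0.51 ± 0.27 for Has1, 0.37 ± 0.25 for Errfi1 and 0.12 ± 0.17 for Rcan1. The difference between the genotypes was not past the threshold for any of them. It was -1.59 ± 0.39 for Has1 (edgeR adjusted p = 0.994), -1.68 ± 0.36 for Errfi1 (edgeR adjusted p = 0.777) and -1.16 ± 0.24 for Rcan1 (edgeR adjusted p = 0.777). The lowest edgeR adjusted p, 0.230, belonged to the circadian repressor gene Bhlhe40 (-1.35 ± 0.21), whose mean was 78.7 and 149.9 CPM in WT air and nicotine and 122 and 91.3 CPM in KO air and nicotine. Next among negative differences were the Wnt antagonist gene Sfrp4 (-1.61 ± 0.31), Cd33 (-2.10 ± 0.44) and Apold1 (-2.72 ± 0.58), none past the threshold. Among positive ones were Vipr1 (2.03 ± 0.48), Cdk5rap1 (1.16 ± 0.30), Rin1 (1.24 ± 0.33), Magt1 (0.55 ± 0.15) and Epm2aip1 (0.60 ± 0.18), also not past it.

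As lists, 16 of 38 had a lower nicotine effect in KO than in WT by camera and 0 a higher one, and none passed with an estimated correlation. With the adipocyte covariate 15 were lower and 3 higher, as without WT air 9, while 14 were lower and 3 higher without KO nicotine 5, and 16 lower and 1 higher without KO air 2. Cytokine, chemokine and adhesion genes differed by a median of -0.73, 17 of 19 being below 0. Their camera adjusted p was 2.70e-12 (adjusted p = 0.129 with an estimated correlation), with 5 members lower when adjusted over the list alone, among them Sele (-2.79 ± 0.66), Ccl2 (-2.96 ± 0.86) and Cxcl1 (-1.88 ± 0.58). Immediate early genes differed by a median of -0.87, 21 of 22 being below 0, with a camera adjusted p of 1.85e-11 (adjusted p = 0.397 with an estimated correlation). Egr2 (-3.76 ± 0.90) and Fosl2 (-1.10 ± 0.29) were lower when adjusted over the list alone. Macrophage markers differed by a median of -0.74, 18 of 19 being below 0, with a camera adjusted p of 5.08e-10 (adjusted p = 0.397 with an estimated correlation). Fcgr3 (-1.30 ± 0.34), Mrc1 (-0.89 ± 0.27) and Csf1r (-0.88 ± 0.28) were lower when adjusted over the list alone. Class II antigen presentation genes differed by a median of -1.56, 7 of 7 being below 0, with a camera adjusted p of 9.07e-10 (adjusted p = 0.397 with an estimated correlation). Of these, 4 were lower when adjusted over the list alone, including H2-Aa (-1.67 ± 0.52) and Cd74 (-1.69 ± 0.55). No member of these 4 lists passed over all genes. KO minus WT, the macrophage score differed by 0.33 in air and -0.36 in nicotine, the cytokine score by 0.50 and -0.63, the class II score by 0.96 and -0.37 and the immediate early score by 0.28 and -0.80. Single libraries moved several of these values. In air, without KO air 7 the macrophage, cytokine and class II differences became 0.16, 0.28 and 0.62. The immediate early difference in air became -0.01 without WT air 8, 0.16 without WT air 9, 0.68 without WT air 10, 0.04 without KO air 1 and 0.51 without KO air 2. In nicotine, the macrophage difference became -0.16 without WT nicotine 6, -0.64 without KO nicotine 3 and -0.19 without KO nicotine 5, and its camera call in nicotine (adjusted p = 0.000109, adjusted p = 0.660 with an estimated correlation) ended without WT nicotine 6 (0.134) and without KO nicotine 5 (0.0718). The class II difference in nicotine became -0.12 without WT nicotine 6, -0.70 without WT nicotine 12, -0.64 without KO nicotine 4 and -0.12 without KO nicotine 5. The contractile gene Acta2 had an interaction of 0.16 ± 0.34.

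For the interaction, edgeR called 0 of 14621 genes, with 647 at an unadjusted p under 0.05 against 731 expected, limma voom called 0, and DESeq2 called 8, all with a lower effect in KO. The edgeR count was 1 without WT nicotine 12, 1 without KO nicotine 3 and 1 without the filter on low counts. No list passed with an estimated correlation (lowest adjusted p = 0.129) or by fry (lowest adjusted p = 0.210). Across the 14621 genes, the nicotine log2 fold changes of WT and KO, which share no libraries, had a Pearson correlation of 0.138 and a Spearman correlation of 0.211. Genes are not independent replicates, so chance was taken from 100 of the 200 possible relabellings of the libraries within each genotype, the real one counted. Their Pearson values ran from -0.327 to 0.261, and 40 of the 100 were as large in size as the real value. Their Spearman values ran from -0.394 to 0.321, and 20 of the 100 were as large in size. The Pearson correlation was 0.278 over genes with at least 5 CPM, 0.0107 without WT air 9 and -0.000618 without WT nicotine 12. No chance level was computed for these alternative values.

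The comparison of KO with WT in room air asked whether the genotypes differed without nicotine, and no gene passed. On the higher side in KO the lowest unadjusted p belonged to the interferon-inducible GTPase gene Gbp4, at 8.73 ± 2.03 CPM in WT air and 26.1 ± 7.66 CPM in KO air (SD, n = 3 each), a log2 fold change of 1.58 ± 0.32. It was followed by Bhlhe40 (0.64 ± 0.15), Abhd6 (0.69 ± 0.16), Gpm6a (1.83 ± 0.44) and Jchain (2.38 ± 0.59), none past the threshold. Genes on the lower side included Wdr12 (-0.64 ± 0.13), Net1 (-0.78 ± 0.17), Klhdc8a (-1.19 ± 0.26) and Proser2 (-1.05 ± 0.23), none past it. Heat shock genes were lower in KO as a list, 15 of 15 being below 0, with a median of -0.83. Their camera adjusted p was 2.60e-12 (adjusted p = 0.419 with an estimated correlation). Hspa8 was at -1.03 ± 0.31 and Hsph1 at -1.63 ± 0.52, and no member passed over all genes or adjusted over the list alone. The heat shock score was 8.19, 7.38 and 7.14 in WT air 8, 9 and 10, and the KO minus WT difference of -0.82 became -0.51 without WT air 8. Lipid synthesis genes were higher, 15 of 15 being above 0, with a median of 0.80 and a camera adjusted p of 2.07e-10 (adjusted p = 0.419 with an estimated correlation). Elovl6 was at 1.52 ± 0.54 and Fasn at 1.27 ± 0.62, again with no member past either threshold. General adipocyte markers were higher too, 15 of 17 being above 0, with a median of 0.25 and a camera adjusted p of 0.0238 (adjusted p = 0.911 with an estimated correlation). The adipocyte call ended without WT air 9 (camera adjusted p = 0.739, downward), WT air 10 (0.124) or KO air 2 (0.696). WT air 9 had the lowest adipocyte and lipid synthesis scores of the air libraries, 6.26 and 6.91, against 8.20 and 8.49 in WT air 8, and the lipid synthesis score difference of 0.94 became 0.61 without WT air 9. Class II antigen presentation genes were higher, with a median of 1.07 and a camera adjusted p of 3.86e-09 (adjusted p = 0.419 with an estimated correlation). With 0 members past the threshold over all genes, 6 of the 7 were higher when adjusted over the list alone, among them H2-Aa (1.21 ± 0.37) and Cd74 (1.07 ± 0.39). Their score difference of 0.96 became 0.62 without KO air 7. Macrophage markers (15 of 19 above 0, median 0.45, camera adjusted p = 8.26e-05) and cytokine genes (15 of 19, median 0.51, 0.000429) were also higher, with adjusted p = 0.640 and 0.419 with an estimated correlation and no member past either threshold. Both calls ended without KO air 7 (camera adjusted p = 0.0903 and 0.0609), the score differences of 0.33 and 0.50 becoming 0.16 and 0.28, and the macrophage call ended with the hepatocyte covariate (0.0683). Mesothelial markers were above 0 in 9 of 9, with a median of 2.46 and a camera adjusted p of 3.92e-06 (adjusted p = 0.419 with an estimated correlation), and no member passed either threshold. The mesothelial score difference of 1.40 became 0.72 without KO air 7. The mesothelial genes Msln and Upk3b reached 17.4 and 28.4 CPM in KO air 7 and at most 1.97 and 2.72 CPM in KO air 1 and 2.

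For KO against WT in air, edgeR called 0 genes (637 at an unadjusted p under 0.05, 731 expected, lowest adjusted p = 0.711), limma voom 0, DESeq2 12, and edgeR on the 6 air libraries alone 2. Camera called 12 lists up and 5 down, 17 in all, against 11 without WT air 9 and 11 with the hepatocyte score of each library as a covariate. No list passed with an estimated correlation (lowest adjusted p = 0.419) or by fry (lowest adjusted p = 0.575).

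Under nicotine vapor, KO libraries had less Rcan1 than WT libraries, at 26.1 ± 4.09 against 69.7 ± 12.6 CPM (SD, n = 3 each). Its log2 fold change was -1.42 ± 0.17, with an edgeR adjusted p of 0.0191, and it was the 1 gene called of 14621. Just outside the threshold, each at an edgeR adjusted p of 0.0537, were Errfi1 (-1.78 ± 0.26), Fosl2 (-1.35 ± 0.21), Sfrp4 (-1.48 ± 0.22), Cttnbp2nl (-0.91 ± 0.14) and Tnfaip6 (-1.90 ± 0.30). Tnfaip6, which encodes a hyaluronan-binding protein, was at 12.2 ± 1.52 CPM in WT and 3.26 ± 0.847 CPM in KO. The lowest unadjusted p among genes with higher values in KO belonged to Epm2aip1 (0.61 ± 0.12), Dbt (0.62 ± 0.13), Mre11a (0.67 ± 0.15), Zfp810 (0.86 ± 0.19) and Krba1 (0.60 ± 0.15), none past the threshold. Heat shock genes were lower in KO, 14 of 15 being below 0, with a median of -1.08. Their camera adjusted p was 5.30e-17 (adjusted p = 0.165 with an estimated correlation). None passed over all genes and 8 fell when adjusted over the list alone, among them Bag3 (-1.38 ± 0.25), Dnajb1 (-2.29 ± 0.48) and Hsph1 (-1.95 ± 0.52). Hspa1b was at 874 ± 463 CPM in WT nicotine and 66.0 ± 22.6 CPM in KO nicotine, but in WT air it ranged from 75.0 to 703 CPM. Its counts are uncertain because the near-identical copy Hspa1a shares its reads.

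Immediate early genes were also lower in KO under nicotine, 22 of 22 being below 0, with a median of -0.68. Their camera adjusted p was 2.86e-13 (adjusted p = 0.322 with an estimated correlation). No member passed over all genes, and 5 fell when adjusted over the list alone, among them Fosl2, Egr2 (-2.87 ± 0.64) and Klf6 (-0.63 ± 0.15). Of the cytokine, chemokine and adhesion genes, 14 of 19 were below 0, with a median of -0.60 and a camera adjusted p of 2.06e-07 (adjusted p = 0.165 with an estimated correlation). None passed over all genes and 8 fell when adjusted over the list alone, among them Nfkbia (-0.60 ± 0.14), Ccl7 (-2.22 ± 0.57) and Sele (-1.57 ± 0.46). The 7 neutrophil markers were all below 0, with a median of -2.06 and a camera adjusted p of 8.93e-06 (adjusted p = 0.256 with an estimated correlation). S100a8, S100a9, Cxcr2 and Retnlg fell when adjusted over the list alone, with none over all genes. The neutrophil score difference of -1.12 became -0.57 without WT nicotine 6. Skeletal muscle markers were higher in KO, 13 of 13 being above 0, with a median of 1.17 and a camera adjusted p of 0.00781 (adjusted p = 0.777 with an estimated correlation). That call ended without WT nicotine 6 (camera adjusted p = 0.274) and without KO nicotine 3 (camera adjusted p = 0.372, downward), and it turned downward with the hepatocyte covariate (camera adjusted p = 0.0353).

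In this comparison 1220 genes had an unadjusted p under 0.05 against 731 expected, limma voom called 1 gene and DESeq2 75 (15 higher, 60 lower). The edgeR count was 4 without WT nicotine 12, 2 without KO nicotine 3, 0 without KO nicotine 4 and 0 without KO nicotine 5. It was 9 with the adipocyte score as a covariate, 6 with DESeq2 size factors or with counts thinned to the smallest total, 7 without the filter on low counts, and 0 with the hepatocyte score, the immediate early score or 1 surrogate variable. Rcan1 itself had an edgeR adjusted p of 0.210 without KO nicotine 4, 0.0848 without KO nicotine 5, 0.0947 without WT nicotine 11 and 0.0670 with only the nicotine libraries in the fit. Its log2 fold change was -1.34, -1.38, -1.33 and -1.41 in those 4 fits, and -1.50 with the hepatocyte covariate (edgeR adjusted p = 0.115). Camera called 2 lists up and 12 down, against 7 up and 12 down without KO nicotine 5 and 0 up and 15 down with the hepatocyte covariate. None passed with an estimated correlation (lowest adjusted p = 0.165) or by fry (lowest adjusted p = 0.191).

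Averaged over the genotypes, nicotine gave no gene past the threshold. On the higher side the lowest unadjusted p belonged to Has1 (log2 fold change 1.30 ± 0.19, edgeR adjusted p = 0.132), Errfi1 (1.21 ± 0.18), the hyaluronan precursor enzyme gene Ugdh (0.62 ± 0.10), Rcan1 (0.70 ± 0.12) and Tsc22d3 (0.84 ± 0.14). On the lower side it belonged to Slc8a3 (-0.96 ± 0.18), Fam212b (-0.97 ± 0.19), Adam19 (-0.59 ± 0.12), Fam84a (-0.99 ± 0.20) and Bmf (-0.77 ± 0.17). Contractile smooth muscle genes fell as a list, 15 of 17 being below 0, with a median of -0.39. Their camera adjusted p was 9.22e-11 (adjusted p = 0.564 with an estimated correlation). Over all genes 0 members passed, while 13 fell when adjusted over the list alone, among them Lmod1 (-0.64 ± 0.16), the tropomyosin genes Tpm1 (-0.42 ± 0.14) and Tpm2 (-0.46 ± 0.14), and Acta2 (-0.41 ± 0.17). Macrophage markers rose, 18 of 19 being above 0, with a median of 0.45 and a camera adjusted p of 9.22e-11 (adjusted p = 0.564 with an estimated correlation). None passed over all genes and 8 rose when adjusted over the list alone, among them Mrc1 (0.69 ± 0.14), Lyve1 (0.74 ± 0.17) and Cd68 (0.62 ± 0.18). The macrophage score rose by 0.81 in WT and by 0.12 in KO, so the average came mostly from WT. In KO it was 4.83, 4.05 and 3.94 in KO nicotine 3, 4 and 5, against 4.06, 3.90 and 4.51 in KO air 1, 2 and 7. Glucocorticoid-responsive genes rose, 13 of 14 being above 0, with a median of 0.56 and a camera adjusted p of 1.23e-09 (adjusted p = 0.155 with an estimated correlation). Errfi1, Tsc22d3, Ddit4 (0.75 ± 0.22) and Per1 (0.47 ± 0.14) rose when adjusted over the list alone, with none over all genes.

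Markers of other tissues moved with these lists when the genotypes were averaged. Skeletal muscle markers had a median of 1.46 and a camera adjusted p of 1.53e-06 (adjusted p = 0.619 with an estimated correlation), and 8 members rose when adjusted over the list alone, with none over all genes. Their score difference of 1.09 became 0.69 without KO nicotine 3, and that of adipocyte markers, 0.65, became 0.42 without WT air 9. All 17 general adipocyte markers were above 0, with a median of 0.60 and a camera adjusted p of 2.86e-06 (adjusted p = 0.630 with an estimated correlation). Oxidative phosphorylation genes rose as a list (camera adjusted p = 0.000224, adjusted p = 0.658 with an estimated correlation) but turned downward with the adipocyte covariate (camera adjusted p = 3.12e-06). Fatty acid oxidation genes (camera adjusted p = 0.000189, adjusted p = 0.637 with an estimated correlation) and lipid synthesis genes (camera adjusted p = 0.0189, adjusted p = 0.658 with an estimated correlation) did likewise (camera adjusted p = 0.0142 and 0.00580). The call of oxidative phosphorylation genes ended without KO nicotine 4 (camera adjusted p = 0.0778). The call of lipid synthesis genes ended without WT air 9 (camera adjusted p = 0.149), WT air 10 (0.112), KO air 1 (0.0995) or KO nicotine 4 (0.477). The average had 1600 genes at an unadjusted p under 0.05 against 731 expected, with 0 called by edgeR, 0 by limma voom and 92 by DESeq2 (67 higher, 25 lower). The edgeR count was 38 without WT air 8, 4 without WT air 10, 3 without WT nicotine 12, 3 without KO nicotine 5, 6 without the filter on low counts and 1 with the hepatocyte score as a covariate. Camera called 15 lists up and 2 down, and none passed with an estimated correlation (lowest adjusted p = 0.155) or by fry (lowest adjusted p = 0.0804).

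The scores of the lists were also compared with 2-sided exact permutation tests among 42 library measures in each contrast. For nicotine against air the lowest p belonged to the vascular tone score, 4.22 ± 0.08 against 4.07 ± 0.05 (SD, n = 6 each; exact permutation p = 0.00649, adjusted p = 0.273), a list whose tested members were 12 above and 12 below 0 (camera adjusted p = 0.972). The glucocorticoid-responsive score was higher by 0.58 (exact permutation p = 0.0152, adjusted p = 0.273). The contractile smooth muscle score was 9.88 ± 0.22 in the 6 nicotine libraries and 10.22 ± 0.18 in the 6 air libraries (SD; exact permutation p = 0.0195, Benjamini-Hochberg adjusted p = 0.273). The macrophage score was higher by 0.46 in nicotine (exact permutation p = 0.0476, adjusted p = 0.400), by 0.81 within WT and by 0.12 within KO. The skeletal muscle score was higher by 1.09 in nicotine (exact permutation p = 0.0368, adjusted p = 0.386). The heat shock score was 6.88 ± 0.29 in the 6 KO and 7.93 ± 0.62 in the 6 WT libraries (exact permutation p = 0.00433, adjusted p = 0.182). The score of 29 hepatocyte genes was 3.09 ± 1.99 in KO and 0.96 ± 1.01 in WT libraries (exact permutation p = 0.0281, adjusted p = 0.591). Between groups of 3 the exact test cannot go below p = 0.1. There the macrophage score was 3.82 ± 0.06 in WT air and 4.63 ± 0.35 in WT nicotine (exact permutation p = 0.1, adjusted p = 0.525). The immediate early score was 6.05 ± 0.71 and 7.08 ± 0.39 (exact permutation p = 0.2, adjusted p = 0.56), and the adipocyte score 7.18 ± 0.97 and 8.09 ± 0.07 (exact permutation p = 0.4, adjusted p = 0.724). For total counts, genes with a count and the mitochondrial share the lowest exact permutation p was 0.154, for the total count of nicotine against air libraries. None of these 42 measures had an adjusted p under 0.05 in any contrast. Between groups of 3 no measure could have reached it. Between 6 and 6 libraries the smallest possible exact permutation p is 0.00216, so 1 measure alone could not pass after adjustment over 42.

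**Figure D3:**
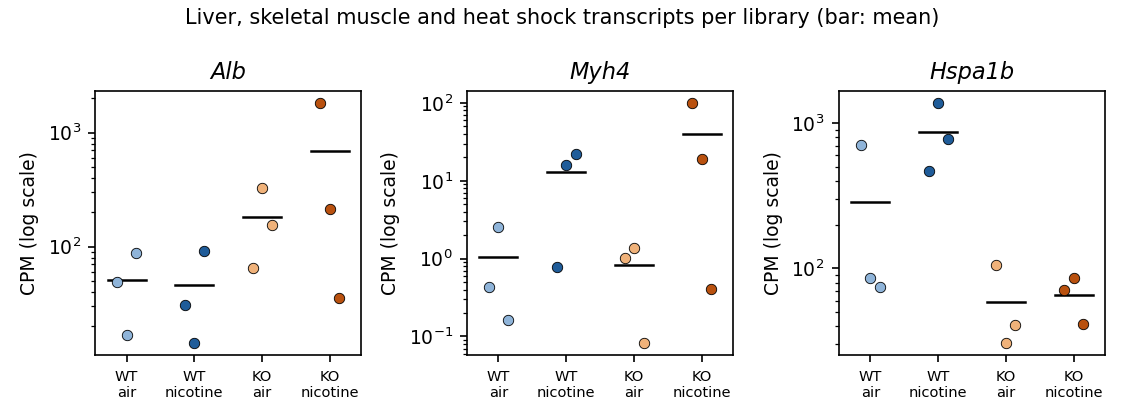
CPM (vertical axis, log scale) of the liver gene Alb, the skeletal muscle gene Myh4 and the heat shock gene Hspa1b in the 4 groups (horizontal axis), with a point per library and a bar for the mean of 3. Alb reaches 1815 CPM in KO nicotine 3 and at most 327 CPM in the other 11 libraries, and Myh4 reaches 99.7 CPM in the same library.

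The authors' deposited table for WT lists 123 genes with an adjusted p under 0.05 (112 higher and 11 lower with nicotine), and the authors' deposited table for KO lists 7 (4 higher, 3 lower). DESeq2 fitted here to the 6 libraries of each genotype alone gave the same counts as the authors' deposited tables. In the authors' deposited table for WT, the lowest adjusted p belongs to Errfi1 (log2 fold change 2.05, adjusted p = 3.98e-11), followed by Fosl2 (1.23), Igfbp6 (0.99), Rcan1 (1.28), Has1 (2.10), Apold1 (2.71) and Ccl2 (2.92). Of the 123 genes in the authors' deposited table for WT, 121 were tested here, and all 121 had the same sign in edgeR's fit. Of these, 117 had an unadjusted p under 0.05 here and 3 an adjusted p under 0.05. The 7 genes of the authors' deposited table for KO are Jchain (log2 fold change -2.62), Zbtb16 (0.82), Adprhl1 (-2.57), Gm13889 (-0.75), Gpx3 (1.38), Gmpr (1.21) and Adamts1 (0.63). All 7 had the same sign here, 5 had an unadjusted p under 0.05 and 0 an adjusted p under 0.05. Across genes, the log2 fold changes of edgeR and of the authors' deposited tables had a Pearson correlation of 0.9997 in WT and 0.9999 in KO.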

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

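Tests chosen only after the result was seen were the lower smooth muscle share, the time of day, all 3 on liver transcripts, the genes around Chrna7, the hepatocyte and immediate early covariates, DESeq2 with only the compared groups, the reading of the macrophage camera call with the adipocyte covariate and the WT calls without KO nicotine 3.

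The nicotine effect differed between the genotypes in 16 gene lists by camera's test of the interaction, none of which passed with an estimated correlation. The median difference, KO minus WT, was -0.73 for inflammatory cytokines, -0.87 for immediate early genes, -0.74 for macrophage markers and -1.56 for class II antigen presentation. It was -1.82 for neutrophil, -0.79 for B cell, -0.86 for T cell and -0.84 for red cell markers, and -0.74 for interferon-stimulated genes. It was -0.34 for fibroblast markers, -0.51 for matrix proteases and their inhibitors, -0.19 for elastic and collagen matrix, -0.89 for mesothelial markers, -0.52 for lipid synthesis, -0.28 for NADPH oxidase and -0.23 for hypoxia and glycolysis. Leaving out 1 library ended 7 of these calls. B cell ended without WT nicotine 6 (camera adjusted p = 0.326), NADPH oxidase without WT air 8 (0.0613) or WT nicotine 6 (0.129), and mesothelial without KO air 7 (0.474) or KO nicotine 5 (0.228). T cell ended without WT air 8 (camera adjusted p = 0.127), WT nicotine 6 (0.326), WT nicotine 11 (0.0662), KO air 1 (0.121), KO air 7 (0.0720) or KO nicotine 5 (0.129). Red cell ended without WT air 8 (camera adjusted p = 0.0572), WT air 10 (0.0721), WT nicotine 6 (0.775), KO air 1 (0.0543) or KO nicotine 4 (0.0967), and with the hepatocyte covariate (0.0658). Hypoxia and glycolysis ended without WT air 9 (camera adjusted p = 0.110), KO air 2 (0.0953) or KO nicotine 5 (0.0906), and with the adipocyte covariate (0.0669). Elastic and collagen matrix ended without WT air 8 (camera adjusted p = 0.308), WT air 10 (0.0904), WT nicotine 6 (0.245), WT nicotine 12 (0.0796), KO air 1 (0.453), KO air 7 (0.136), KO nicotine 3 (0.217) or KO nicotine 4 (0.734), and with the hepatocyte covariate (0.309). Among calls that held, the score difference moved from -1.12 to -0.56 for neutrophil and from -0.64 to -0.40 for interferon-stimulated genes without WT nicotine 6, and from -0.96 to -0.64 for lipid synthesis without WT air 9.

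For these lists chance cannot be excluded, since 37 of 100 regroupings of the 12 libraries, the real one counted, gave as many lists as the real 16, with 25 the most in another. For genes of the interaction all 100 regroupings gave as many calls as the real 0, which any regrouping must, so this tests nothing about chance, while 1 called 721. That regrouping set WT air 8 with WT nicotine 11 and 12 against WT nicotine 6 with WT air 9 and 10. In KO it set KO air 2 with KO nicotine 3 and 4 against KO air 1 and 7 with KO nicotine 5. It was picked as the most extreme after it was seen, and its cause was not tested. The oxidative phosphorylation score was 7.32 to 8.04 in the libraries named first in each genotype. In the others it was 6.45 to 7.065. The fatty acid oxidation score also separated them, at 6.83 to 7.69 against 5.69 to 6.53. The general adipocyte score overlapped, at 8.01 in WT nicotine 12 and 8.15 in WT nicotine 6.

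Macrophage markers were higher with nicotine in WT, their score rising by 0.81 (SE 0.28). A lower share of smooth muscle would raise other non-muscle cell markers alike. The macrophage score rose by 0.63 (SE 0.22) more than the mean of the endothelial, fibroblast, T cell and Schwann scores. These lists were chosen after the result was seen. Of the other marker lists, neutrophil (1.28), skeletal muscle (0.93), adipocyte (0.91) and mesothelial scores (0.84) rose by more than the macrophage score. Brown adipocyte (0.45), red cell (0.20) and B cell scores (0.14) rose by less, and hepatocyte (-0.10) and cardiac muscle scores (-0.16) fell. The result thus depends on the lists compared, so a lower share of smooth muscle stays open as a cause of the macrophage rise. With the adipocyte score as a covariate the rise was 0.83 (SE 0.34) and the camera call held (adjusted p = 5.21e-16), while oxidative phosphorylation and fatty acid oxidation genes turned downward, which argues against adipose content as the whole cause. This is thin evidence, since without the covariate the list passed neither with an estimated correlation (adjusted p = 0.304) nor by fry (adjusted p = 0.155), and the bound set beforehand for the rise that remains was not met, so a part from adipose content stays open, and a biological effect of nicotine, which the design names, may also remain. With 10 splits of the 6 WT libraries, too few for a share under 0.05, 1 gave as many lists as the real 20, which was the real split itself, with 17 the most in another.

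Has1, Rcan1 and Errfi1 were higher with nicotine in WT by a mean log2 difference of 1.77 (SE 0.14). With the immediate early score as a covariate it was 1.67 (SE 0.19) and with the adipocyte score 1.76 (SE 0.18), although edgeR then called 0 genes. The 3 genes were called for this difference in these same libraries, which favours a large difference and a small spread within groups. A covariate could then hardly change the difference, so these fits are weak evidence against either score as the whole cause. Covariates that take the same degree of freedom, the hepatocyte score and 1 surrogate variable, gave 4 and 3 calls, and why the calls ended was not tested further. Time of day at harvest is not stated, and a clock index differed by -0.54 with an SE of 0.68, so it may contribute. The index was 1.21 to 2.54 in WT nicotine, where the mean log2 CPM of the 3 genes was 5.89 to 5.96. WT air 8, KO nicotine 5 and KO air 1 had indices of 1.19, 1.95 and 2.40, but means of only 4.18, 4.28 and 4.30. As far as the index follows time of day, these values argue against it as the whole cause. Of the 10 splits, too few for a share under 0.05, 2 gave as many genes as the real 3, the real split being 1 of them, with 3 the most in another.

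KO nicotine 3 held liver transcripts, with Alb at 1815 CPM. All 29 hepatocyte genes were highest of the 12 libraries in it, in line with liver RNA in that library as a candidate explanation. A library of another tissue in its place is argued against by its contractile score, which lay -0.45 from the mean of the other 11 (SD 0.24). Only 1 KO nicotine library had more Alb than the highest KO air library. Alb was at 213 and 35.5 CPM in KO nicotine 4 and 5, against 64.9, 327 and 154 CPM in KO air 1, 2 and 7. The hepatocyte scores were 3.17 and 0.95 against 1.43, 3.79 and 2.71. These values argue against a response to nicotine shared by the KO nicotine libraries. For KO nicotine 3 alone the count restates the pattern, so a response in that library stays open.

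The other counts are given as values, and each count of splits, regroupings or relabellings includes the real one. With 10 splits each, too few for a share under 0.05, nicotine in KO gave the real 0 genes in 10 splits (0 the most in another) and the real 15 lists in 5 (20 the most). KO against WT in air gave the real 0 genes in 10 (0 the most) and the real 17 lists in 3 (23 the most). KO against WT in nicotine gave the real 1 gene in 2 (1 the most) and the real 14 lists in 6 (23 the most). For nicotine averaged over genotypes, chance cannot be excluded for lists, as 23 of 100 regroupings gave as many as the real 17 (23 the most). All 100 gave as many genes as the real 0 (2 the most), and no count of 0 in this paragraph tests chance, since every regrouping reaches it. Nor can chance be excluded for the correlation between the nicotine effects of WT and KO, real value 0.138, where 40 of 100 relabellings were as large in size and the largest other was 0.327.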

How the results depend on the processing

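Alternatives chosen only after the data were seen were the hepatocyte and immediate early covariates, DESeq2 with only the compared groups and the WT calls without KO nicotine 3. Where a count changed, the cause was not tested, except that leaving out a library or a group also leaves fewer libraries. Of 10978 alternative values of the named genes, 10620 kept their direction and side of the threshold, 207 came past it, 26 were no longer past it, 125 changed sign while not called, and 0 reversed while called. The 4 called values kept their call in 57 of 83. Genes called for nicotine in WT (3) became 7 with DESeq2 size factors, 21 without a filter on low counts, 0 with the adipocyte covariate, 0 with the immediate early covariate, 0 with only the compared groups, 99 with DESeq2 and 123 with DESeq2 on only the compared groups. Leaving out each WT library or KO nicotine 3 in turn gave 0 (without WT air 9) to 34 (without WT air 8). Nicotine in KO (0) became 7 with DESeq2 on only the compared groups. The interaction (0) became 1 without a filter and 8 with DESeq2, and 0 to 1 without each library. KO against WT in air (0) became 2 with only the compared groups, 12 with DESeq2 and 41 with DESeq2 on only those groups. KO against WT in nicotine (1) became 6 with DESeq2 size factors, 7 without a filter, 9 with the adipocyte, 0 with the hepatocyte and 0 with the immediate early covariate, 0 with 1 surrogate variable, 6 with thinned counts, 75 with DESeq2 and 71 with DESeq2 on only the compared groups, and 0 (without KO nicotine 4) to 4 (without WT nicotine 12). The average (0) became 6 without a filter, 1 with the hepatocyte covariate and 92 with DESeq2, and 0 (without WT air 9) to 38 (without WT air 8). Gene lists became 0 with an estimated correlation and 0 with fry in all 6 comparisons. Lists for KO against WT in air (17) became 11 with the hepatocyte covariate, and 11 (without WT air 9) to 20 (without WT air 8). Of 99 list calls, 68 were kept with the adipocyte covariate, 82 with the hepatocyte covariate and 99 with DESeq2 size factors. No paired analysis was possible because library numbers are unique and the groups share none. At this depth, 29 of 100 simulated 2-fold interactions were recovered, in a simulation that draws genes independently.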

Other observations

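Chosen only after the result was seen were the comparison of KO with WT averaged over exposures and the test of the genes around Chrna7.

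With both exposures averaged, the 6 KO libraries had lower values than the 6 WT libraries for several genes, none past the edgeR threshold. Tnfaip6 was at 8.62 CPM in WT and 2.81 CPM in KO (log2 fold change -1.49 ± 0.21, edgeR adjusted p = 0.0679), and Rcan1 differed by -0.84 ± 0.12 at the same edgeR adjusted p. Rcan1 differed mainly under nicotine, at 55.3 to 78.8 CPM in WT and 23.2 to 30.8 CPM in KO. In air its libraries overlapped, at 26.2 to 30.5 CPM in WT and 21.4 to 29.1 CPM in KO. Tnfaip6 was lower in KO in both, at 1.82 to 2.81 against 3.31 to 5.93 CPM in air and 2.29 to 3.85 against 10.5 to 13.5 CPM in nicotine. Nedd9, a scaffold of focal adhesions, was at 158 CPM in WT and 103 CPM in KO (-0.61 ± 0.10), and the highest KO library (117 CPM) lay below the lowest WT library (129.6 CPM). Net1, a guanine nucleotide exchange factor for RhoA, differed by -0.72 ± 0.12. EdgeR called 0 of 14621 genes here, with 1229 at an unadjusted p under 0.05 against 731 expected.

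Strain DNA carried along with a knocked-out gene could change the genes beside it, a hypothesis tested on the 20 tested genes nearest to Chrna7. Their mean size of log2 fold change between KO and WT was 0.13, at percentile 7.72 of 13295 runs of 20 neighbouring genes (median 0.20, 95th percentile 0.40). Of the 20, 0 had an unadjusted p under 0.05 in edgeR (lowest edgeR adjusted p = 0.613), which argues against a large effect of this kind and does not check the genotype.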
